A study of Mus musculus with 12 samples.

How the data were processed

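The study measured RNA on 12 arrays of the Toray 3D-Gene mouse chip, read for Cy5 at 635 nm, from 4 T cell fractions sorted from Peyer's patches (DN, CD4, CD8 and γδ) with 3 arrays each. Per the file headers, the array files hold the median intensity of each spot and of the area around it, without background correction or normalization, from scans at 3 gains. The deposited value table of the series holds intensity on a linear scale: within each array it is a straight line of the spot signal that crosses 0 near the mean of the blank spots, scaled to a median of 25 and left empty for spots not above background. The labels do not state how the authors made that table, so its description comes from the values. Groups were taken from the sample labels and never from the values.

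Each array holds 27456 spots, of which 3982 are controls or empty, and 23473 different probes. A gene symbol was given by the probe table supplied with the series for 20690 probes (19321 symbols), 2783 probes had none, and 0 had several. No symbol changed when Entrez IDs were looked up in a gene table of mouse, where 134 IDs were missing. 25 probes marked by the scanner software on at least 1 array were left out. A probe counts as detected where the value table lists it. The local background rose with the brightness of its own spot (correlation across spots 0.948 to 0.987 per array), so it was not subtracted. There were 2736 blank spots on the arrays of replicate 1 and 384 on the others. 1 spot of 1 array was at the scanner limit, that of Ccl5 in DN 1. Signal over background limits what dim genes can show: the mean of the blank spots lay at 58.6 to 62.2 and the median spot at 70.7 to 77.9.

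The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for figures. Spot medians were corrected with normexp (offset 50), taken to log2 and quantile normalised between arrays. Genes were tested where a probe was detected on all 3 arrays of at least 1 fraction, with the probe of the highest mean kept for each symbol and unnamed probes set aside, which left 16942 genes. lmFit fitted the means of the 4 fractions over all 12 arrays, with eBayes, two-sided tests and Benjamini-Hochberg adjustment over the genes of each comparison, called at adjusted p under 0.05. 6 comparisons between fractions, the F test over all 4, and the overlap of the 3 DN comparisons were made. 25 gene lists were tested in the 3 DN comparisons with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, with adjustment over the lists of a comparison. fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. These choices and the lists were made before the data were examined.

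The offset narrows the differences of dim genes. Among genes called without the libraries labelled CD8 1 and γδ 1, the median size of the log2 difference was 0.42, 0.50 and 0.53 for DN vs CD4, DN vs CD8 and DN vs gd, and 1.07, 1.10 and 0.80 on the value table, with the same sign in 100%, 99.95% and 100% of genes. A fold given as at least a value is for a gene detected on 0 arrays of the lower fraction: values of that fraction under the lowest signal of a detected probe of their array were raised to it before the means were compared. On the value table, empty values were set to the lowest listed value of the array, so a difference that rests on one is given as at least that value.

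Genes were named by a rule. It takes the sort genes, the 8 highest and the 8 lowest log2 differences among genes called whose 3 values in DN lie all above or all below those of the other fraction and which are detected on all 3 arrays of the higher fraction, without clone names, up to 3 called members of each list with the smallest adjusted p, every measured gene of the MHC class II list, and the 8 genes with the largest smallest difference among those higher or lower in DN than in each other fraction. The same rule was applied without the libraries labelled CD8 1 and γδ 1. Foxp3, Cd79b, Ms4a1 and the second probes are outside this rule and were chosen after their values were seen.

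The replicate numbers were checked for pairing. After the mean of each fraction was taken off, the correlations across genes between arrays of different fractions with the same number were above 0.1 in 18 of 18 pairs (0.100 to 0.735), and for 10 of 12 arrays the best partner in another fraction had the same number. The number goes with the array series: replicate 1 is series H (4 arrays) and replicates 2 and 3 are series B (8 arrays). The check therefore cannot tell samples paired by number from a shift between the series. Values with the replicate number and with the array series as a block are given. Replicates 2 and 3 of a fraction correlated at 0.997 to 0.998 across genes, with an SD of the log2 difference of 0.083 to 0.111, against 0.359 to 0.371 between replicate 1 and the others in DN and CD4 and 0.507 to 0.529 in CD8 and γδ. They shared no identical spots.

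The tests were tried on simulated data with the spread of these arrays and 200 changed genes of 16942. With the spread as labelled, 77% of genes changed by a log2 of 1 and 85% of those changed by 2 were recovered, with 173 calls of which 6.36% were false. With the spread without the libraries labelled CD8 1 and γδ 1, it was 86% and 99%, with 199 calls of which 7.04% were false. No gene was called in the wrong direction. These shares hold for the simulated data only. Shifts shared by the arrays of a series, close replicates, correlated genes and libraries that go against their labels may change them. They are therefore no measure of the recovery or the false calls in the real comparisons.

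Alternatives chosen before the data were examined were the replicate number or the array series as a block, replicates 2 and 3 alone, median scaling, no background correction, the value table, no filter on dim probes, detection on all 12 arrays, only the arrays of the fractions compared, array weights, a log2 difference of at least 1, all probes, eBayes with a trend, each library left out in turn, and the set tests above. The alternatives without both doubted libraries, the same with the array series as a block, a normexp offset of 16, and a floor at the 5th percentile in the value table were added after seeing the data. The T cell receptor loci could not be read since their probes have no symbol. No genome coordinates are given, since the build of the probe table is not named. Local background, the further scanner gains and control spots other than blanks were not used here.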

Results

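The data are 12 arrays, each hybridised with the Cy5-labelled RNA of T cells sorted from Peyer's patches, the lymphoid follicles in the wall of the small intestine, of C57BL/6 mice. Cells were pooled from 3 to 5 male and female mice aged 10 weeks, and the labels state a purity above 98% after the sort. Per the labels there are 4 fractions with 3 arrays each, numbered 1 to 3. The γδ fraction carries the γδ T cell receptor, the DN fraction carries TCRβ but neither CD4 nor CD8β, and the CD4 and CD8 fractions carry TCRβ with CD4 or with CD8β. The gate did not use CD8α, so DN cells may hold CD8αα homodimers. The median spot signal of an array lay between 70.7 and 77.9 intensity units, against 58.6 to 62.2 for the mean of its blank spots, and 18930 to 21394 of 23473 probes were detected per array. The number of arrays limits the precision. The labels state that RNA collection was repeated 3 times but not that each round used separate mice, so the p-values measure the spread between these samples. Replicates 2 and 3 of a fraction correlated at 0.997 to 0.998 across genes, and counts from replicates 2 and 3 alone may rest on technical spread only. The array names fall into 2 series: replicate 1 of every fraction is in a series of 4 arrays and replicates 2 and 3 are in a series of 8 arrays.

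The genes of the sort markers separate the fractions, with an exception in a pair of libraries. Cd4 had a log2 signal of 8.76, 9.97 and 9.72 in the CD4 libraries and between 6.00 and 6.16 in the other 9. Cd8b1, which encodes the CD8β chain, stood at 6.29, 6.26 and 6.28 in the DN libraries and at 13.80 and 13.62 in the libraries labelled CD8 2 and CD8 3. The library labelled CD8 1 had a Cd8b1 signal of 8.57, and the library labelled γδ 1 had 13.91, where γδ 2 and γδ 3 had 8.29 and 8.14. Both values go against the labels. Cd8a, which encodes the CD8α chain, was high in DN (14.42, 14.35 and 14.22), CD8 and γδ libraries alike and stood at 7.75 to 7.96 in the CD4 libraries. Cd163l1, a scavenger receptor of γδ T cells, had a log2 signal of 8.23 in the library labelled CD8 1, 8.57 and 8.48 in γδ 2 and γδ 3, and 6.11 in γδ 1. The genes of the T cell receptor chains have no symbol in the gene table of the array, so 3 of 13 sort genes could be read. All values below keep the labels, and each main count is also given without the libraries labelled CD8 1 and γδ 1, an alternative chosen after seeing the data.

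**Figure D1:**
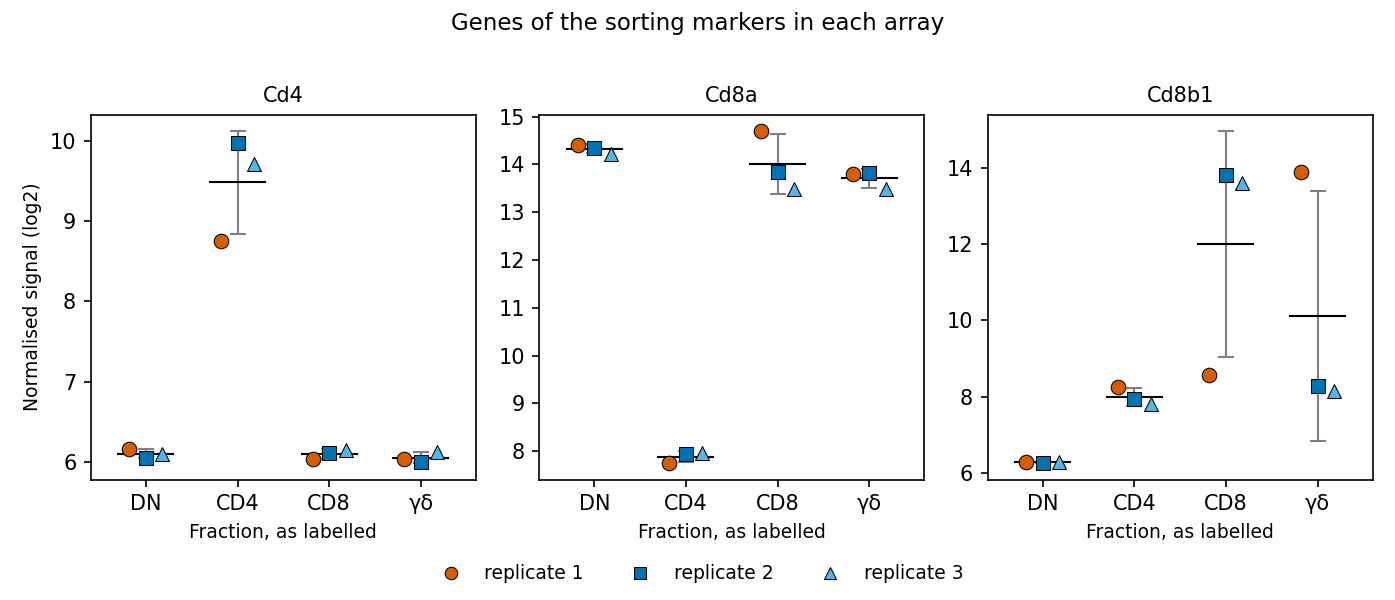
Log2 normalised signal of Cd4, Cd8a and Cd8b1 (y axis) in each of the 12 arrays by labelled fraction (x axis), with points for arrays, black lines for means and grey bars for 1 SD. Cd8b1 is at 8.57 in the library labelled CD8 1 and at 13.91 in the library labelled γδ 1.

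The comparison of DN with CD4 cells asks how T cells without CD4 and CD8β differ from helper T cells of the same tissue. Among the genes higher in DN cells were receptors of natural killer cells: Klrd1, the CD94 subunit of such receptors, had a log2 signal of 13.51 ± 0.27 in DN and 7.43 ± 0.11 in CD4 libraries (SD, n = 3 each). The log2 difference was 6.08 ± 0.63 (SE, adjusted p = 0.00149), and that of Klra6, a receptor of the Ly49 family, was 4.65 ± 0.53 (adjusted p = 0.00246). Among the genes lower in DN cells, Izumo1r, a folate receptor family member of regulatory T cells, had a log2 difference of -5.45 ± 0.69 (adjusted p = 0.00425). That of Il4, the cytokine interleukin 4, was -3.36 ± 0.16 (adjusted p = 9.3e-06), and that of Tnfsf11, the cytokine RANKL, was -3.43 ± 0.11. In each gene named here and called in a DN comparison as labelled, all 3 DN values lay on 1 side of all 3 values of the other fraction. For genes called only without the libraries labelled CD8 1 and γδ 1, this holds among the libraries kept, and in several of them the library left out overlaps DN.

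Of 16942 genes, 386 differed between DN and CD4, 141 higher and 245 lower in DN. Some genes, such as Fcer1g and H2-Eb1, given below, differed by more than Gzmb but were not called. Among the genes called and named by the rule, the others with the highest log2 differences were Gzmb, a granzyme (5.10 ± 0.94, adjusted p = 0.0285), Klra5 of the Ly49 family (5.03 ± 1.03, 0.041), the chemokine genes Xcl1 (4.66 ± 0.92, 0.0378) and Ccl5 (at least 4.32, 0.0215), the granule gene Nkg7 (4.07 ± 0.71, 0.0219) and Ncf1, a subunit of the NADPH oxidase (3.83 ± 0.69, 0.025). On the lower side were Cd5, a brake on T cell receptor signals (-3.54 ± 0.66, 0.03), the growth factor receptor gene Igf1r (-3.40), Sh2d1a, an adaptor of follicular helper T cells (-3.32), Sostdc1 (-3.31) and the costimulatory receptor gene Tnfrsf4 (-3.25). The spot of Ccl5 in DN 1 was at the scanner limit, and Ccl5 is among the brightest spots of all DN libraries, so its difference is a lower bound. The offset used on dim signals narrows these differences: on the deposited value table, the log2 difference was 7.14 for Klra6, 7.74 for Klra5, -6.63 for Il4, -5.88 for Sostdc1 and -5.37 for Cd5. Of 39 genes named and called in this comparison, 19 kept the call without any 1 of the 12 libraries, Klrd1, Klra6, Izumo1r, Il4, Tnfsf11, Igf1r, Sostdc1 and Tnfrsf4 among them. Gzmb, Klra5, Xcl1, Ccl5, Nkg7, Ncf1, Cd5 and Sh2d1a lost it in at least 1 such run. The highest adjusted p was 0.147 for Xcl1, 0.145 for Klra5 and 0.127 for Cd5 without CD4 2, 0.11 for Gzmb and Ncf1 and 0.103 for Nkg7 without DN 3, and 0.09 for Ccl5 and 0.0691 for Sh2d1a without DN 2. Ly49 genes have near-identical sequences, so a probe may read more than 1 of them.

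The gene lists fixed before the data were examined place these genes in groups. In the list of natural killer receptors and unconventional T cells, 4 of 16 genes were higher in DN than in CD4 and 13 when adjusted over the list alone, with a median log2 difference of 1.87 (camera adjusted p = 2.67e-15). The adjusted p was 0.108 with an estimated correlation. Besides Klrd1 and Xcl1, Itgae, the αE integrin that binds E-cadherin, differed by 3.80, although its second probe differed by 0.52, and Klrc1, an NKG2 receptor, by 1.41. Klrc1 was detected on 0 of the 3 CD4 arrays and was at least 2.53-fold higher in DN. The cytotoxic effector list had 4 of 17 genes higher, Gzmb, Ccl5, Nkg7 and the protease gene Ctsw (3.59), 9 when adjusted over the list alone, and a median of 0.67 (camera adjusted p = 1.98e-08). Its adjusted p was 0.145 with an estimated correlation. When the libraries labelled CD8 1 and γδ 1 were left out, the adjusted p with an estimated correlation was 0.00748 for natural killer receptors, 0.025 for cytotoxic effector, 0.00528 for follicular helper T and 0.0116 for regulatory T genes. With the array series as a block added it was 0.0335, 0.0483, 0.0252 and 0.0335 in that order. Without DN 2, the adjusted p was 0.11 for Ctsw and 0.09 for Itgae. The follicular helper T list fell, with 9 of 14 genes lower (10 when adjusted over the list alone) and a median of -1.49 (camera adjusted p = 7.41e-20, and adjusted p = 0.000201 with an estimated correlation), among them Tbc1d4 (-3.00). The regulatory T list had 4 of 11 genes lower (7 when adjusted over the list alone), including the receptor genes Gpr83 (-1.68), Il2ra (-1.34) and Tnfrsf18 (-0.62), and a median of -0.61 (camera adjusted p = 1.21e-07, and adjusted p = 0.00476 with an estimated correlation). Foxp3, the transcription factor of regulatory T cells, differed by -0.24 (adjusted p = 0.147).

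The series is titled after antigen presentation by these cells, and the list of MHC class II presentation bears on it. Of its 13 genes, 0 passed limma's test between DN and CD4 as labelled, 7 passed when adjusted over the list alone, and the median log2 difference was 1.63 (camera adjusted p = 6.64e-05). The adjusted p was 0.209 with an estimated correlation. H2-Eb1, H2-Aa and H2-Ab1, which encode chains of the class II molecules, differed by 5.11, 5.07 and 3.13 (adjusted p = 0.112, 0.147 and 0.127), and the invariant chain gene Cd74 by 5.09 (0.112). The peptide loading genes H2-DMb1, H2-DMa, H2-Ob and H2-Oa differed by 2.29, 1.63, 2.16 and 1.43, Ifi30 by 1.36 and Lgmn by 0.43. The class II transactivator gene Ciita differed by -0.40, Ctss by -0.31 and Rfx5 by -0.16. Without the libraries labelled CD8 1 and γδ 1, the differences are the same and 8 of the 13 genes were higher in DN, with adjusted p = 1.44e-05 for H2-Aa and 2.41e-05 for Cd74. The adjusted p of the list was then 0.0701 with an estimated correlation.

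B cell genes moved with the MHC class II genes. In the B cell list, 1 of 18 genes was higher in DN than in CD4 (Ebf1, a B lineage transcription factor, 0.38), which lost its call in 8 of 12 runs that left out a library (highest adjusted p 0.139 without DN 3) and whose other probes differed by 0.26 and 0.08. In the list 14 were higher when adjusted over the list alone, and the median was 1.36 (camera adjusted p = 1.18e-13). The adjusted p was 0.145 with an estimated correlation. Cd79b, a chain of the B cell receptor complex, differed by 4.69 (adjusted p = 0.054), Blnk, an adaptor of that receptor, by 4.51 (0.0929) and Ms4a1, which encodes CD20, by 4.30 (0.071). With the libraries labelled CD8 1 and γδ 1 left out, 14 of 18 were higher, the adjusted p of the list was 0.0505 with an estimated correlation, and the mean log2 signal of the list was 8.06, 8.63 and 8.65 in the DN libraries, 6.51 to 6.57 in CD4, 8.27 and 8.29 in γδ 2 and γδ 3, and 6.46 and 6.48 in CD8 2 and CD8 3. The library labelled CD8 1 had a mean of 7.62 and the library labelled γδ 1 of 6.51.

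**Figure D2:**
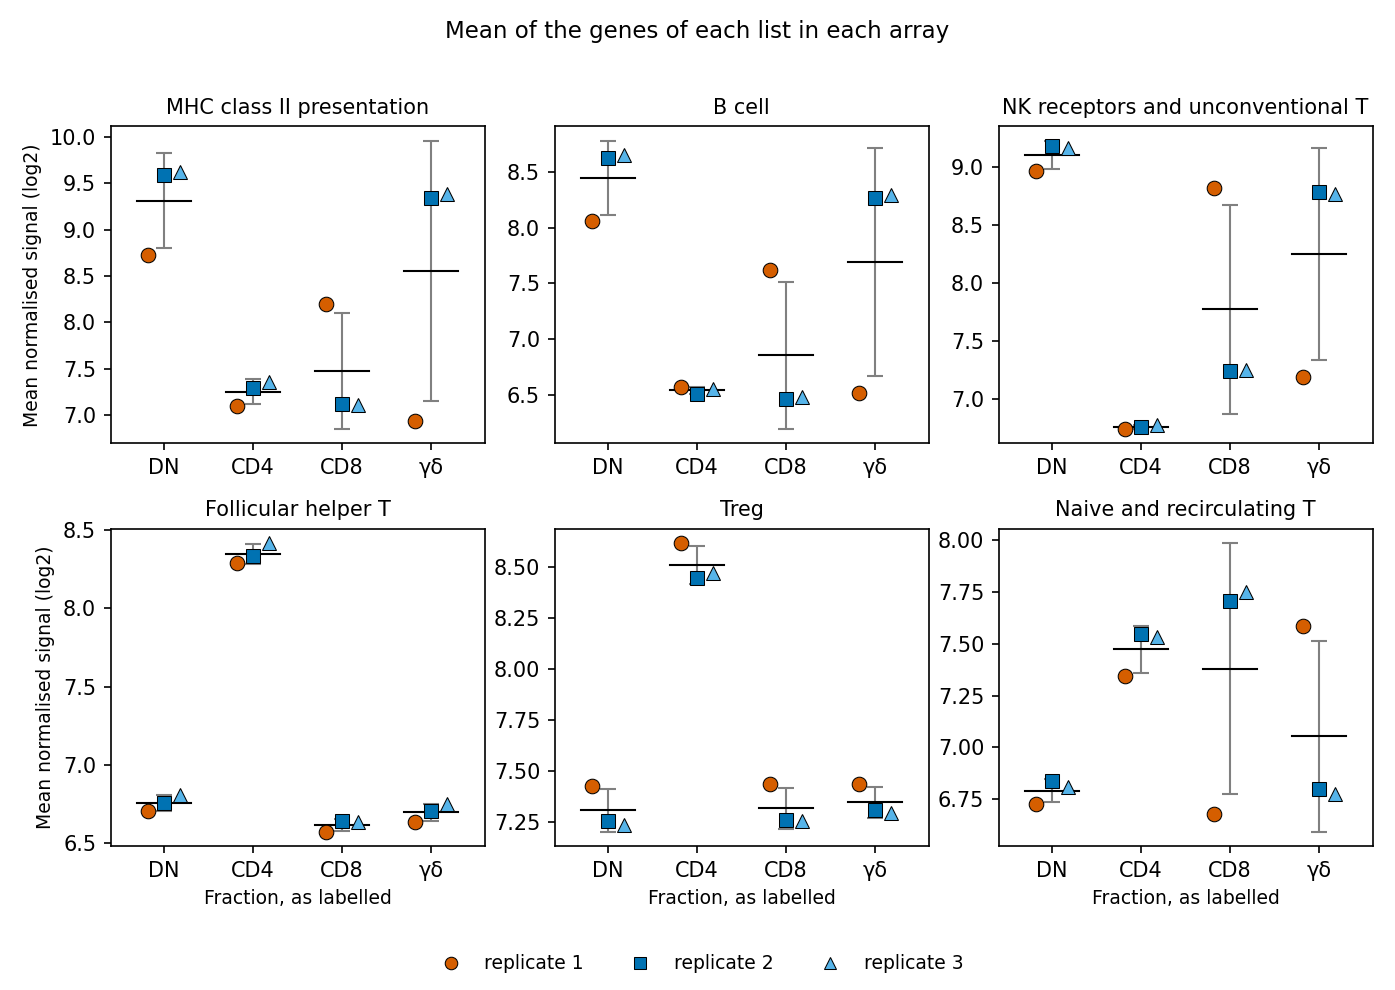
Mean log2 normalised signal of 6 gene lists (y axis) in each of the 12 arrays by labelled fraction (x axis), with points for arrays, black lines for means and grey bars for 1 SD. The B cell list is at 8.06 to 8.65 in the DN libraries and at 6.51 to 6.57 in the CD4 libraries.

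Of the other theme lists between DN and CD4, the T cell receptor complex and proximal signalling list had 2 of 18 genes lower, Cd5 and the adaptor gene Lcp2 (-0.67), 9 when adjusted over the list alone, and a median of -0.77 (camera adjusted p = 1.19e-06). Its adjusted p was 0.145 with an estimated correlation. The naive and recirculating T list had a median of -0.30 and 0 of 14 genes called by limma (camera adjusted p = 0.00287), and its adjusted p was 0.397 with an estimated correlation. In the list of Fc receptors and uptake, 2 of 16 genes were higher (5 when adjusted over the list alone), the IgG receptor genes Fcgr2b (0.55, detected on 1 of the 3 CD4 arrays) and Fcgr3 (0.48), with a median of 0.02, a mean of 0.54 and a camera adjusted p of 0.00877. That list had an adjusted p of 0.1 with an estimated correlation. Fcer1g, the signalling chain of several Fc and natural killer receptors, differed by 6.69 (adjusted p = 0.104, and 7.05e-09 without the libraries labelled CD8 1 and γδ 1). Isg15 (-1.43) was the 1 of 13 interferon response genes called lower (3 when adjusted over the list alone), with a list median of -0.15 (camera adjusted p = 0.00149). That adjusted p was 0.202 with an estimated correlation. The inhibitory and tolerance list had 2 of 22 genes lower, Pdcd1, which encodes PD-1 (-1.52), and Tnfrsf18, with a median of -0.16 (camera adjusted p = 0.27). When adjusted over the list alone, 4 of its genes were higher and 4 lower. With 1 library left out, the adjusted p rose to 0.154 for Fcgr2b (without DN 2), 0.142 for Pdcd1 (without CD4 2), 0.0795 for Lcp2 and 0.0593 for Fcgr3 (both without CD4 3), and 0.127 for Cd5 (without CD4 2). The adjusted p with an estimated correlation and without the libraries labelled CD8 1 and γδ 1 was 0.0881 for T cell receptor signalling, 0.0116 for naive and recirculating T, 0.0386 for Fc receptor and 0.025 for interferon response genes. With the array series as a block added it was 0.0978, 0.0335, 0.0961 and 0.109 in that order. Camera did not call the lists of costimulation (median 0.08, camera adjusted p = 0.0766), type 17 (-0.02, 0.259) and cell cycle genes (-0.04, 0.848).

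Among other cell types and signs of RNA quality, camera called the intestinal epithelium list higher in DN than in CD4 (median 0.22, adjusted p = 1.32e-07), with 1 of 19 genes called by limma, the antimicrobial lectin gene Reg3b (1.20), and 9 when adjusted over the list alone. The adjusted p was 0.145 with an estimated correlation. The plasma cell list had a median of 0.13 (camera adjusted p = 0.000714) and the dendritic cell list of 0.05 (0.00149), with 3 genes each when adjusted over the list alone. Their adjusted p was 0.198 and 0.0555 with an estimated correlation. All 3 lists had an adjusted p of 0.025 with an estimated correlation when the libraries labelled CD8 1 and γδ 1 were left out. With the array series as a block added it was 0.0953 for intestinal epithelium, 0.0483 for plasma cell and 0.067 for dendritic cell genes. Camera adjusted p was above 0.05 for the lists of germinal centre B cells (median -0.02, with Fas at -0.54), macrophages and monocytes (-0.02, with the chemokine receptor gene Ccr2 at -1.03), granulocytes and mast cells (0.01, with Gata1 at -0.54), stroma and endothelium (-0.01, with Acta2 at -0.59) and erythroid cells (-0.07, 2 genes). It was also above 0.05 for immediate early and dissociation stress genes (-0.12, with Egr2 at -1.10), ribosomal protein genes (-0.14) and mitochondrial respiratory chain genes (-0.02). With 1 library left out, the adjusted p rose to 0.176 for Gata1 and 0.0722 for Egr2 (both without CD4 3), and to 0.134 for Ccr2 and 0.0889 for Fas (both without DN 2). On the value table camera called the stress (adjusted p = 0.0407), ribosomal (0.0144), mitochondrial (0.0387) and type 17 lists (0.047) lower in DN than in CD4. Against CD8 it called the ribosomal (0.00068) and mitochondrial lists (0.0216) lower there, and against γδ the ribosomal (0.000312), mitochondrial (0.000763), T cell receptor signalling (0.0033) and type 17 lists (0.0282). None of these kept its call with an estimated correlation, where the lowest adjusted p was 0.127. By fry, which does not compare a list with other genes, the lists of stroma (adjusted p = 0.0211), erythroid (0.0285), mitochondrial (0.0431), type 17 (0.0431) and stress genes (0.0132) were lower and costimulation (0.0346) was higher.

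The count of DN vs CD4 genes depends on the spread that all 12 arrays share. It was 1796 (860 higher and 936 lower) without the libraries labelled CD8 1 and γδ 1, 896 with the replicate number as a block, 1437 with the array series as a block and 4805 among replicates 2 and 3 alone. The series that holds replicate 1 has 1 array per fraction, so it gives no test. Leaving out a single library gave 993 without CD8 1, 774 without γδ 1, 256 without γδ 2, 139 without DN 2, 128 without DN 3, 146 without CD4 2 and 145 without CD4 3. Of the genes called, 36.5% were higher in DN, against 52.7% with the value table and 27.4% with median scaling.

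DN and CD8 cells share TCRβ and differ by the gate in CD8β, so their comparison asks what goes with the lack of that chain. As labelled, 3 of 16942 genes differed, all higher in DN. Klrc1 differed by 1.17 ± 0.11 (adjusted p = 0.0148), Myl1, a myosin light chain of muscle, by 1.06 ± 0.08 (0.00304) and Klra16, a gene of the Ly49 family, by 0.96 ± 0.06 (0.00147). On the value table the log2 difference was 3.72 for Klrc1, 3.92 for Myl1 and at least 4.90 for Klra16, which is empty there in CD8 3, and Klrc1 was not called on that scale (adjusted p = 0.0905). The call for Klrc1 was lost in 7 of 12 runs that left out a library, with a highest adjusted p of 0.14 without DN replicate 2, while Myl1 and Klra16 kept theirs.

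The low count goes with the spread among the libraries labelled CD8, in which Cd8b1 itself had an SD of 2.97 and a difference of -5.72 ± 1.69 from DN (adjusted p = 0.422). Without the libraries labelled CD8 1 and γδ 1, 2190 genes differed, 1013 higher and 1177 lower in DN (4489 with the array series as a block added), and Cd8b1 differed by -7.43 ± 0.13 (adjusted p = 2.18e-07). In that setting Fcer1g was higher by 6.42 ± 0.06, H2-Aa by 6.00 ± 0.26, Cd74 by 5.85 ± 0.28, Blnk by 5.17 ± 0.27 and the chemokine receptor gene Ccr6 by 4.39 ± 0.19. Lower in DN were Ramp1, a receptor activity modifying protein (-3.19 ± 0.06), the naive T cell transcription factor gene Lef1 (-2.87 ± 0.15) and the cytokine receptor gene Il7r (-1.94 ± 0.11). The second probe of Ramp1 differed by -0.42. Without the libraries labelled CD8 1 and γδ 1, CD8 holds only CD8 2 and CD8 3, of 1 array series, and DN holds arrays of both. The spread between series within CD8 is therefore not measured by these SEs and p-values.

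Of the lists between DN and CD8 as labelled, natural killer receptors and unconventional T had 1 of 16 genes called (8 when adjusted over the list alone) and a median of 1.18 (camera adjusted p = 4.02e-14). The B cell list had a median of 1.31 (6.19e-16) and MHC class II presentation of 1.56 (1.76e-07), with 0 genes called by limma in either, and 15 of 18 and 7 of 13 when adjusted over the list alone. The adjusted p of these 3 lists was 0.159 with an estimated correlation. The naive and recirculating T list had a median of -0.30 (camera adjusted p = 0.000636), with an adjusted p of 0.392 with an estimated correlation. Camera also called the lists of cytotoxic effector (median 0.54, adjusted p = 0.00747), intestinal epithelium (0.19, 9.64e-08), plasma cell (0.16, 5.82e-05), dendritic cell (0.04, 0.00263), cell cycle (0.19, 0.0102), tolerance (0.06, 0.0113) and Fc receptor genes (0.03, 0.0421) higher. It called T cell receptor signalling (-0.30, 0.0113) and interferon response genes (-0.15, 0.000346) lower. With an estimated correlation the adjusted p of these 9 lists was 0.159 or more. In the type 17 list the median was -0.01 and the mean 0.12, and in the stress list 0.04 and -0.02, and camera called neither. With the libraries labelled CD8 1 and γδ 1 left out, 12 of 16 natural killer receptor genes, 13 of 18 B cell genes and 8 of 13 MHC class II genes were higher in DN, and 10 of 14 naive and recirculating T genes were lower. The adjusted p with an estimated correlation was then 0.0123 for natural killer receptors, 0.0123 for naive and recirculating T, and 0.0875 for both B cell and MHC class II genes. Of the other 9 lists it was 0.0298 for plasma cell, 0.0427 for interferon response and 0.0483 for intestinal epithelium genes, and 0.0608 or more for the rest. With the preset correlation camera then no longer called Fc receptor genes (adjusted p = 0.092) and called ribosomal protein genes lower (0.0394, and 0.157 with an estimated correlation). With the array series as a block added, the adjusted p with an estimated correlation was 0.0545 for plasma cell genes. It was 0.117 for interferon response and for intestinal epithelium genes.

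The DN vs CD8 count was 22 with the replicate number as a block, 79 with the array series as a block and 5517 among replicates 2 and 3 alone. It was 11 without DN 1, 1149 without CD8 1, 7 without γδ 1, 5 with median scaling, 5 with all probes and 7 with a trend in eBayes. It was 1 with detection on all 12 arrays, which leaves out Klra16 and Klrc1. With only the arrays of DN and CD8 it was 0 in limma, with 1346 genes at an unadjusted p under 0.05 and an adjusted p of 0.301 for Myl1 and Klra16 and 0.183 for Klrc1. As labelled over all arrays, 1480 genes passed at an unadjusted p under 0.05.

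The comparison of DN with γδ cells sets TCRβ cells without CD4 and CD8β beside cells with the γδ receptor. Cd8b1 stood at 8.29 and 8.14 in γδ 2 and γδ 3, above all DN libraries. As labelled, 2 of 16942 genes differed, both higher in DN: Myl1 by 1.02 ± 0.08 (adjusted p = 0.00424) and Klra16 by 0.96 ± 0.06 (0.00142), or 3.41 and at least 4.65 on the value table, where Klra16 is empty in γδ 3 and Myl1 was not called (adjusted p = 0.0674). Both kept the call without any 1 of the 12 libraries and lost it with only the arrays of DN and γδ (adjusted p = 0.221 for Myl1 and 0.13 for Klra16). Without the libraries labelled CD8 1 and γδ 1, 164 genes differed, 63 higher and 101 lower in DN, and 1061 differed with the array series as a block added. Klra6 was then higher by 3.44 ± 0.07, Klra5 by 2.60 ± 0.09 and Klre1, a further natural killer receptor gene, by 1.55 ± 0.09, and Cd163l1 was lower by a log2 difference of -2.44 ± 0.05 (adjusted p = 2.07e-06). The costimulatory receptor gene Cd28 was higher in DN by 1.15 ± 0.14 (adjusted p = 0.0176) without those libraries and differed by -0.16 as labelled. Ccl4, a chemokine gene, was lower (-0.90 ± 0.14, 0.0437) and differed by 0.07 as labelled. On the value table Klre1 read 988.5 in the library labelled CD8 1, inside the DN range of 975.4 to 1141.5. It read 348.9 and 294.6 in γδ 2 and γδ 3. Klra6 (349.9) and Klra5 (1326) in the library labelled CD8 1 lay under all DN values.

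Between DN and γδ as labelled, camera called natural killer receptors and unconventional T higher (median 0.85, adjusted p = 1.1e-10, 0 of 16 genes called by limma, 3 when adjusted over the list alone) and likewise the B cell list (0.64, 6.22e-07) and MHC class II presentation (0.62, 0.0304), with 0 genes when adjusted over the list alone. With an estimated correlation the adjusted p was 0.36, 0.431 and 0.463. Intestinal epithelium (median 0.16, camera adjusted p = 5.33e-08), plasma cell (0.21, 0.0318) and Fc receptor genes (0.03, 0.0318) were also higher, and naive and recirculating T (-0.15, 0.0318) and interferon response genes (-0.06, 0.0481) lower. Each of these 5 lists had an adjusted p of 0.36 or more with an estimated correlation. In the follicular helper T list the median was -0.00219 and the mean 0.06, and in the macrophage list -0.03 and 0.01, and camera called neither. With the libraries labelled CD8 1 and γδ 1 left out, the median of MHC class II presentation was -0.11 (camera adjusted p = 0.951) and that of the B cell list 0.12 (0.241). This setting sets DN arrays of both array series against γδ arrays of 1 series. With the array series as a block in it, the medians were 0.17 (camera adjusted p = 0.622) and 0.21 (0.0197), with adjusted p = 0.883 and 0.873 with an estimated correlation. Among replicates 2 and 3 alone, both lists were called higher in DN by camera (medians 0.33 and 0.36, adjusted p = 0.00324 and 1.14e-07), and their adjusted p was 0.166 and 0.0543 with an estimated correlation. Without the block, camera also did not call plasma cell (adjusted p = 0.587), Fc receptor (0.0925), naive and recirculating T (0.907) and interferon response genes (0.835). H2-Aa then differed by 0.43 (adjusted p = 0.598) and H2-Eb1 by -0.11 (0.951), while 4 of 16 natural killer receptor genes were higher (median 0.26, camera adjusted p = 7.48e-06). The adjusted p of that list was 0.117 with an estimated correlation. The type 17 list was lower by camera in that setting (median -0.08, adjusted p = 0.00269), with Cd163l1 and Ramp1 called, and so was the macrophage and monocyte list (-0.11, 0.00339, with Ms4a7 at -0.27), while the intestinal epithelium list was higher (0.12, 0.00212). With an estimated correlation their adjusted p was 0.117, 0.117 and 0.225.

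The DN vs gd count was 5 with the replicate number as a block, 18 with the array series as a block and 2057 among replicates 2 and 3 alone. It was 8 without DN 1, 19 without CD8 1, 6 without γδ 1, 4 with a trend in eBayes or with all probes, and 1 with the value table or with detection on all 12 arrays. With only the arrays of DN and γδ it was 0 in limma, with 969 genes at an unadjusted p under 0.05. As labelled over all arrays, 751 genes passed at an unadjusted p under 0.05. On the value table the median of all genes lay 0.11 higher in DN than in CD8 and 0.20 higher than in γδ without the libraries labelled CD8 1 and γδ 1, and differences on that scale are relative to those shifts.

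Genes that set DN apart from every other fraction are the overlap of the 3 comparisons. As labelled, Klra16 and Myl1 were higher in DN than in each other fraction. The number expected of independent lists is 2.95e-06, which leaves out the shared DN arrays, and 20 simulations of unchanged fractions gave 0, which leaves out real differences. The count was 1 with the value table or with detection on all 12 arrays. Klra16 was detected on 0 of the 3 CD4 arrays and was at least 1.98-fold higher in DN. No gene was lower in DN than in each other fraction in limma's tests, where DN vs CD4 had 2360 genes at an unadjusted p under 0.05. The 3 comparisons share the DN arrays, and 3 arrays cannot be split into parts of at least 2, so a share of the overlap may come from those arrays. With all labelled libraries, the count of genes higher in DN than in each other fraction was 4 with the replicate number as a block and 11 with the array series as a block, and that of lower genes was 0 and 1. Among replicates 2 and 3 alone, 500 were higher and 317 lower. The count of higher genes was 4 without DN 1, 9 without CD8 1 and 4 without γδ 1, and that of lower genes 1 without DN 1 and 8 without CD8 1.

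Without the libraries labelled CD8 1 and γδ 1, 41 genes were higher and 25 lower in DN than in each other fraction, beside 0.191 and 0.388 for independent lists and 0 in 20 simulations of unchanged fractions. Neither figure holds both the shared DN arrays and real differences, so the overlap that these would give by chance is not known. The 8 with the largest smallest difference were Klra6, Klra5, Klre1, Trf (transferrin), Reg3b, Myl1, Klra16 and Klrb1a, a natural killer receptor gene. Against CD4, CD8 and γδ, Klra6 differed by 4.65, 4.53 and 3.44, Klra5 by 5.03, 5.04 and 2.60, Klre1 by 3.95, 3.82 and 1.55, Trf by 2.19, 2.26 and 1.07, and Klrb1a by 2.44, 2.50 and 0.84. Lower were Cd8b1, by -1.72, -7.43 and -1.94, the T cell surface gene Thy1, by -2.60, -2.52 and -1.17, and Bcl11b, a transcription factor that maintains T cell identity, by -2.23, -2.06 and -0.97. Cd8b1 encodes the chain that the gate kept out of DN, so its difference from CD8 was set by the sort. Ramp1 differed by -2.45, -3.19 and -0.85, and the others were Rpl39, Rtf1, Gm4862 and Scp2-ps1, with differences between -1.34 and -0.61. A second probe of Thy1, detected on 9 arrays, differed by -0.01 from CD4. On the value table, Klre1 (988.5) and Klrb1a (769.9) in the library labelled CD8 1, left out here, lay inside the DN ranges. The other genes named as higher in DN lay under theirs in that library. With the array series as a block in this setting, 232 genes were higher and 162 lower.

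**Figure D3:**
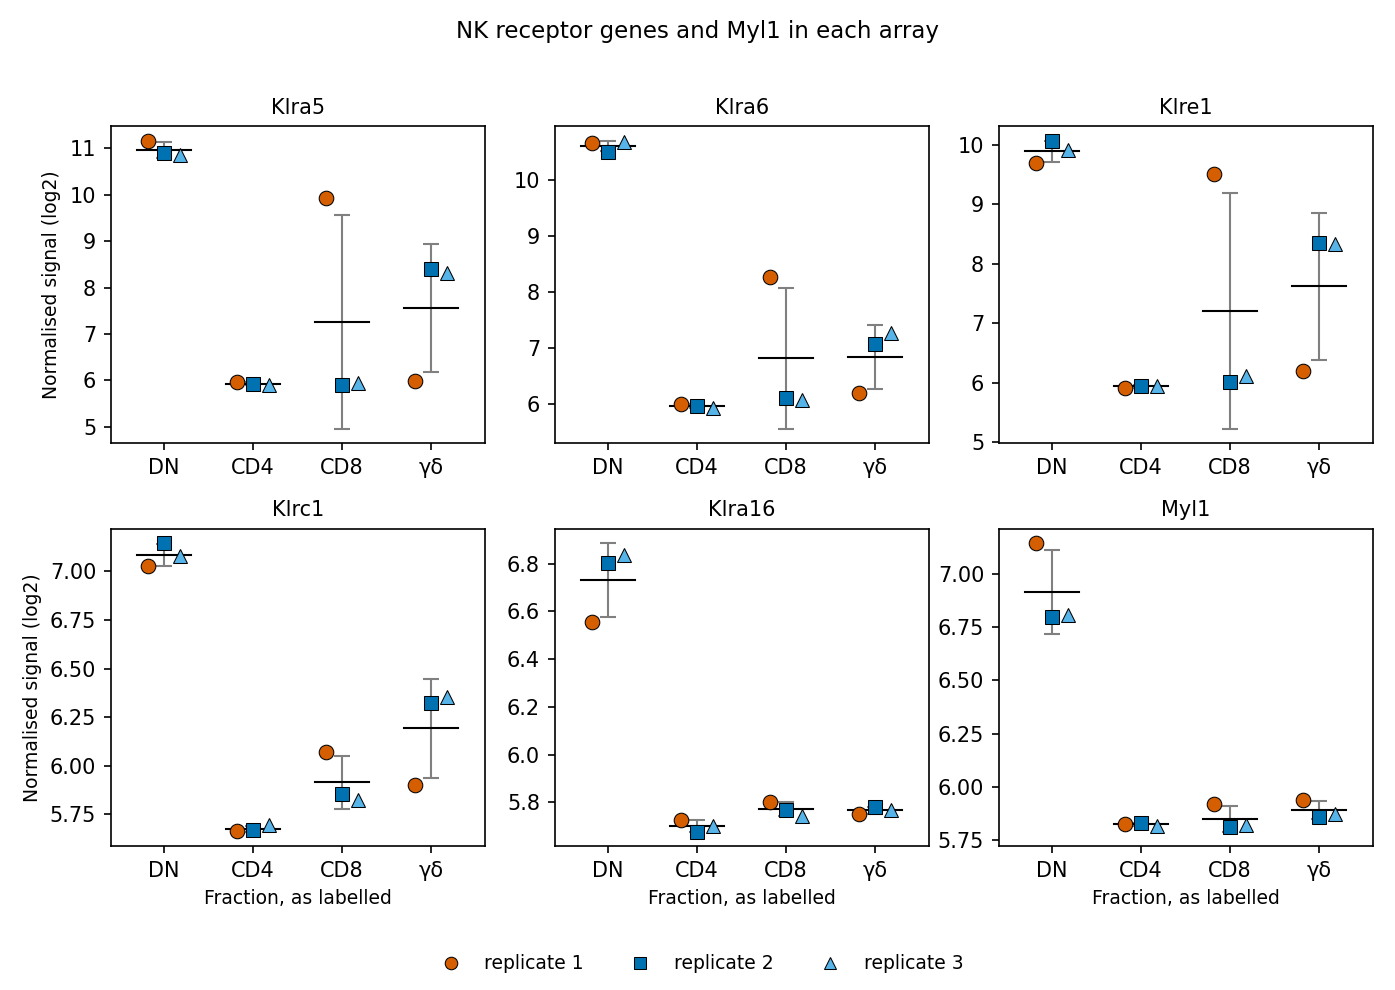
Log2 normalised signal of 5 natural killer receptor genes and Myl1 (y axis) in each of the 12 arrays by labelled fraction (x axis), with points for arrays, black lines for means and grey bars for 1 SD. Klra6 has a mean of 10.61 in the DN libraries and of 5.96 in the CD4 libraries.

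The comparisons among the other fractions give the distance against which DN is read. As labelled, CD4 vs CD8 had 181 genes (151 higher and 30 lower in CD4), CD4 vs gd had 193 (152 higher and 41 lower) and CD8 vs gd had 0, with 331 genes at an unadjusted p under 0.05 in limma. The counts were 914, 1524 and 1250 without the libraries labelled CD8 1 and γδ 1. With the replicate number as a block they were 377, 498 and 0, with the array series as a block 536, 734 and 0, and among replicates 2 and 3 alone 3989, 5126 and 4640. Of the genes called in CD4 vs gd, 78.8% were higher in CD4, against 92.9% with median scaling. CD4 vs CD8 gave 414 genes without CD8 1, 92 without CD4 2, 91 without CD4 3, 88 without CD8 2 and 89 without CD8 3. CD4 vs gd gave 300 genes without CD4 1, 334 without CD8 1, 714 without γδ 1, 94 without γδ 2, 91 without γδ 3, 102 without CD4 2 and 114 without CD4 3, and CD8 vs gd gave 16 without CD8 1 and 12 without γδ 1. Over the 4 fractions, limma's F test gave 200 genes for any difference between the 4 fractions, 2485 without the libraries labelled CD8 1 and γδ 1, 422 with the replicate number as a block, 803 with the array series as a block and 7103 among replicates 2 and 3 alone. It gave 1039 without CD8 1, 646 without γδ 1, 122 without γδ 2, 109 without γδ 3, 111 without DN 2 or DN 3, 76 without CD4 2, 88 without CD4 3, 121 without CD8 2 and 130 without CD8 3.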

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

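The tests in this part on exchanged labels, array series, mixed RNA, B cell RNA and a lower share of T cells were chosen after the result was seen, and those on B cell RNA and a lower share of T cells took their form after other forms had been run. An earlier form, the range of 5 lists without B cells, gave 1.15 (permutation p = 0.0425) over 72 genes and 0.955 (permutation p = 0.0735) over the 33 brighter ones and had left the share of T cells open. Those on dendritic cells and macrophages and on other splits of the arrays were fixed before. Probes without a gene symbol were set aside and tested apart: of 2339, 52 differed between DN and CD4 (29 higher and 23 lower in DN), 2 between DN and CD8 and 2 between DN and γδ. Without the libraries labelled CD8 1 and γδ 1 the counts were 216, 291 and 36. The largest log2 differences were 4.99, 2.76 and 2.77. T cell receptor genes may be among these probes.

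The libraries labelled CD8 1 and γδ 1 differ from replicates 2 and 3 of their own fractions, and an exchange of the 2 labels is a candidate explanation, since 2 of these 2 libraries lay nearer to the other fraction than to their own over all genes without Cd8b1. A difference between the array series is argued against by Cd8b1, which moved by -5.14 in the library labelled CD8 1 and by 5.69 in γδ 1, but by 0.0243 in DN 1 and 0.395 in CD4 1. Cd8b1 is also the gene that raised the doubt about these libraries, so its shifts are no separate evidence. Mixed RNA of CD8 and γδ cells is argued against by a median place of 0.961 in γδ 1 and 0.994 in CD8 1 between their own fraction at 0 and the other at 1, over 370 genes. The quartiles were 0.844 and 1.02 in γδ 1 and 0.709 and 1.15 in CD8 1, so single genes spread widely. These places do not test mixing with RNA of DN or CD4 cells. The library labelled CD8 1 lay nearer still to DN (mean distance 0.0991) than to γδ (0.131), but Cd8b1 and Cd163l1 in it stood with γδ 2 and γδ 3, and its place between DN and γδ had a median of 0.630 over 25 genes with quartiles of 0.0784 and 0.930, too wide to decide. Within series H, the SD of the log2 difference was 0.190 between CD8 1 and DN 1 and 0.284 between γδ 1 and CD4 1. In series B, γδ 2 and DN 2 gave 0.1795, and CD8 2 and CD4 2 gave 0.297. With the labels of the series H pairs, CD8 2 and DN 2 gave 0.410, and γδ 2 and CD4 2 gave 0.405. These distances argue against the 2 labels and go with an exchange. Whether labels or sorted cells were exchanged stays open, so no label was changed.

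Camera with a preset correlation called the lists of MHC class II and B cell genes higher in DN than in CD4, with 0 of 13 and 1 of 18 genes called as labelled and adjusted p = 0.209 and 0.145 with an estimated correlation. RNA of B cells in the DN fraction could produce both, and the test of it cannot decide. On the value table of replicates 2 and 3, the medians in DN minus γδ were 0.50 for B cell and 0.26 for MHC class II genes. They differed by 0.238 ± 0.165 (bootstrap SE). Both lists stood near the DN level in γδ 2 and γδ 3 (B cell list 8.27 and 8.29, against 8.63 and 8.65 in DN 2 and DN 3). Such medians would be small whether B cells in both fractions or the T cells themselves are the source. The B cell median in DN minus CD4 was 3.06 against 2.54 for MHC class II. A lower share of T cells was tested only with all other cell types higher alike, which would raise these lists equally. The median of B cell genes lay 2.82 ± 1.06 (bootstrap SE) above that of 72 genes of 5 other cell types. Macrophages were at -0.0968, stroma at 0.0252 and epithelium at 1.05, although many of these markers are dim. Both SEs resample genes as if independent, while the B cell list had an estimated correlation of 0.674, so they may be too small. The medians lean against an equal rise of all other cell types without excluding it. They do not bear on a lower share of T cells in which B cells rise more than other types, which was not tested. RNA of dendritic cells or macrophages can neither be excluded nor shown, with a higher list median of 0.676. The stated purity above 98% leaves room for a small share of B cells, and whether that would be enough was not tested. Expression of these genes by the T cells themselves was not tested either and stays open.

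Other splits of the arrays give limited information. For each pair of fractions there are 10 splits, too few for a share under 0.05. As many or more genes were called in 1 of 10 splits for DN vs CD4 (386, highest other 0), DN vs CD8 (3, highest other 1), DN vs gd (2, highest other 0), CD4 vs CD8 (181, highest other 2) and CD4 vs gd (193, highest other 0). For CD8 vs gd it was 10 of 10, with 0 genes as labelled. The split of CD8 1, γδ 2 and γδ 3 against the others gave 1290, the highest of the 10. It is the grouping that an exchange of the labels CD8 1 and γδ 1 would give, so the 0 as labelled does not show that CD8 and γδ cells are alike. Among 100 splits into 4 groups, 1 reached the 2 genes higher in DN than in each other fraction, 100 reached the 0 lower genes and 5 reached the 200 genes of any difference. The highest other split gave 1939 genes, which points to structure among these samples. It keeps DN 1 to DN 3 together and puts CD4 1, CD8 1 and γδ 1, all of the array series of replicate 1, in a group of their own, so it follows that series in part. With the array series as a block the labelled fractions gave 803.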

How the results depend on the processing

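The settings without both doubted libraries (those labelled CD8 1 and γδ 1), the value table with a 5th percentile floor and the normexp offset of 16 were chosen after the result was seen, and the others were fixed before. Counts are in the order DN vs CD4, DN vs CD8, DN vs gd, CD4 vs CD8, CD4 vs gd, CD8 vs gd, higher in DN than in each other fraction, lower, and any difference between the 4 fractions. As labelled they were 386, 3, 2, 181, 193, 0, 2, 0 and 200.

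With the replicate block they were 896, 22, 5, 377, 498, 0, 4, 0 and 422, and with the array series block 1437, 79, 18, 536, 734, 0, 11, 1 and 803. MHC class II presentation DN vs gd kept its median of 0.62 and lost its call with either block. So did, with adjusted p for the replicate block, the cytotoxic (0.0831), tolerance (0.0769) and Fc receptor lists (0.0989) DN vs CD8, and the plasma cell (0.089), Fc receptor (0.0946), naive (0.0964) and interferon lists (0.11) DN vs gd. Costimulation (0.0391) and stress genes (0.0391) DN vs CD4 and cell cycle genes DN vs gd (0.0245) gained a call with either block. With only replicates 2 and 3 the counts were 4805, 5517, 2057, 3989, 5126, 4640, 500, 317 and 7103. Without both doubted libraries they were 1796, 2190, 164, 914, 1524, 1250, 41, 25 and 2485, and with the array series block added 4296, 4489, 1061, 2838, 3729, 3375, 232, 162 and 5892. Array weights gave 5026 for DN vs CD4, 5866 for DN vs CD8, 2499 for DN vs gd, 2858 for CD4 vs CD8, 5049 for CD4 vs gd, 4659 for CD8 vs gd, 478 higher in DN than in each other fraction, 341 lower in DN than in each other fraction and 7962 for any difference between the 4 fractions.

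Between DN and γδ, Cd28 changed sign to 1.03 with only replicates 2 and 3, 0.99 with array weights, 1.15 without both doubted libraries and 1.03 with the array series block added. Ccl4 changed sign to -0.73, -0.71, -0.90 and -0.81 in these settings. Naive and recirculating T DN vs gd was -0.0116 with only replicates 2 and 3 and 0.0142 without both doubted libraries and with the array series block. The interferon list DN vs gd went from -0.0632 to 0.00578 with only replicates 2 and 3, 0.00267 with array weights and 0.0206 without both doubted libraries and with the array series block. MHC class II presentation DN vs gd was -0.11 without both doubted libraries, 0.17 with the array series block added and 0.33 with array weights, and the B cell list was 0.12, 0.21 and 0.34 in these settings and 0.36 with only replicates 2 and 3. With only replicates 2 and 3 MHC class II presentation DN vs gd was 0.33. Both lists kept their call by camera with the preset correlation (adjusted p = 0.00324 and 1.14e-07) and were not called with an estimated correlation.

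Camera with an estimated correlation took the call from MHC class II presentation (1.63, 1.56 and 0.62 against CD4, CD8 and γδ) and from the B cell list (1.36, 1.31 and 0.64). fry took it from MHC class II presentation DN vs CD8 (1.56) and DN vs gd (0.62) and from the B cell list DN vs CD8 (1.31) and DN vs gd (0.64).

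Median scaling gave 5 genes for DN vs CD8. The value table of the series matrix gave 1 for DN vs gd, 116 for CD4 vs CD8, 115 for CD4 vs gd, 1 higher in DN than in each other fraction and 121 for any difference, with MHC class II presentation DN vs gd at 0.88 and its call lost (adjusted p = 0.0522), as for the plasma cell and Fc receptor lists (0.0522 each). With a 5th percentile floor it gave 1 for DN vs gd, 119 for CD4 vs gd, 1 higher and 127 for any difference. Detection on all 12 arrays gave 1 for DN vs CD8, 1 for DN vs gd and 1 higher, with MHC class II presentation DN vs gd at 0.54. Only the arrays of the fractions compared gave 870, 0, 0, 51 and 50 for the first 5 counts. A log2 difference of at least 1 gave 122 for DN vs CD4, 1 for DN vs gd, 65 for CD4 vs CD8, 60 for CD4 vs gd, 1 higher and 84 for any difference. All probes gave 5 for DN vs CD8, 4 for DN vs gd and 4 higher, and eBayes with a trend gave 7, 4 and 4. No background correction, no filter and a normexp offset of 16 moved no count by more than 1.5 times.

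With each library left out in turn, the counts ranged from 128 to 993 for DN vs CD4, 2 to 1149 for DN vs CD8, 2 to 19 for DN vs gd, 88 to 414 for CD4 vs CD8, 91 to 714 for CD4 vs gd, 0 to 16 for CD8 vs gd, 2 to 9 higher, 0 to 8 lower and 76 to 1039 for any difference. MHC class II presentation ranged from 1.43 to 2.12 against CD4, 1.40 to 1.83 against CD8 and -0.11 (without γδ 1) to 0.95 against γδ, where its call was also lost without DN 2 (adjusted p = 0.144), DN 3 (0.143) or CD4 1 (0.0535). The B cell list ranged from 1.12 to 1.81, 1.16 to 1.67 and 0.12 to 0.94.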

Other observations

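Without the libraries labelled CD8 1 and γδ 1, a setting chosen after the result was seen, 632 genes were higher and 452 lower in DN than in both CD4 and CD8. The DN arrays stand in both comparisons, and independent lists would overlap in 51.4 and 65 genes, a figure that leaves out those arrays. The same setting left 164 genes between DN and γδ against 1796 for DN vs CD4 and 2190 for DN vs CD8. With the array series as a block added the counts were 1061, 4296 and 4489, and among replicates 2 and 3 alone, of 1 series, 2057, 4805 and 5517. The gap stayed in each setting, and its size changed. The setting without those libraries leaves the series unbalanced in CD8 and γδ.

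The intestinal epithelium list was higher in DN than in CD4, CD8 and γδ by camera as labelled (medians 0.22, 0.19 and 0.16). With an estimated correlation the adjusted p was 0.145, 0.159 and 0.36, and without both doubted libraries 0.025, 0.0483 and 0.225, or 0.0953, 0.117 and 0.509 with the array series block added. The median against γδ was 0.396 in replicate 1, where γδ 1 is doubted, and 0.0425 in replicates 2 and 3, and that against CD4 0.294 and 0.117. Without both doubted libraries Reg3b was higher by 1.06 against γδ. The list's median difference from CD4 of 1.05 on the value table is under that of B cell genes (3.06), and where this RNA comes from was not tested.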
